A study of Homo sapiens with 11 samples.

How the data were processed

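ChIP-seq of JMJD1C and LYL1 and sequencing of input DNA were carried out in 4 acute myeloid leukaemia lines, 11 libraries in all. Every library is its own group, named from its title, and none has a replicate. Per the labels' protocols, crosslinked and sonicated chromatin was precipitated with an antibody made in the submitters' laboratory against the N-terminal part of JMJD1C. The deposited peak list of the Kasumi-1 JMJD1C library was analysed. Per the submitters' processing notes, the genome build was hg19, and Bowtie2 2.1.0 and HOMER were among the tools used.

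Peaks were called with MACS 1.4.2, per the file headers, with a p-value cutoff of 1e-05, an effective genome size of 2.7 Gb, a band width of 300 bp, a model fold range of 10 to 30 and tags of 51 bp. The modelled fragment size was 88 bp, per the file headers. The header names no control, so the authors called these peaks without an input, on 1 library. The caller kept at most 1 tag per position, which removed 32.2% of the tags and left 19897991, and estimated the background of each peak from 10 kb around it, per the file headers. The deposited columns are whole tag counts per peak, a score of 10 times the negative log10 of the Poisson p-value, a fold enrichment (the ratio of the summit to the local background), and start, end, length and summit position. Counts are not normalised. The deposited list has no false discovery rate. Without a control, open or copy-rich DNA and repeats that collect tags can raise the count of called sites, and a background that includes the peak's own tags can lower the fold of long and tag-rich peaks. Depth limits the list at its weak end, where peaks rest on as few as 9 tags. Keeping 1 tag per position also caps the tags a narrow peak can hold.

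Start, end and length matched in all peaks, and no peak was left out. All positions are the deposited hg19 coordinates. The local background was recovered by solving the Poisson tail for the expected tags, with the peak length as window (at least 176 bp, which is 2 fragment sizes). It came out within 0.05 of a whole number of tags per 10 kb, or within 0.15 of the genome-wide minimum of 73.7, in 34616 peaks (95.6%), where the first criterion would be met by 10% of arbitrary values. Of all peaks, 2793 (7.72%) were at the minimum, so their surrounding signal is an upper limit. The surrounding signal is the recovered tags outside the peak, scaled to 10 kb. It was used for 34535 peaks and not for those with a score at its maximum, shorter than 176 bp, longer than 5000 bp or with no whole value. A peak used also had to hold no more tags than its recovered background per 10 kb. An isolated peak had no other peak within 20 kb and was not within 1 Mb of a peak-free stretch of at least 3 Mb. Median intervals are percentile intervals from 2000 bootstrap draws of peaks. Shares have 95% exact Clopper-Pearson intervals and tag numbers exact Poisson intervals. All intervals cover counting error or the spread over peaks within 1 library, and no p-value was computed across peaks.

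Neighbour shares were compared with 1000 random placements per chromosome. Placements were planned outside assembly gaps; no gap table was used here, and the long peak-free stretches were excluded in place of gaps. On simulated peaks with a known background, 100% of 4854 recovered values were within the tolerance. The simulated scores used the same Poisson tail and window as the recovery, so this checks the computation and not the caller's background. Peaks placed at random over the whole span gave a ratio to placement of 0.998, and peaks set in pairs 5 kb apart gave 4.01. These simulated placements did not exclude the long peak-free stretches. Peaks per Mb refer to the span from the first to the last peak of a chromosome. Named sites follow a rule set before the data were examined, the 15 peaks of highest fold on chromosomes 1 to 22 and X; other sites and the segments along chromosomes were chosen afterwards, as were the tag-rich peaks. The stricter threshold, the minimum fold of 10, the chromosome filter and the distances of 2 and 50 kb were also set before the data were examined.

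The promoter share, the random-promoter comparison, promoter against distal fold, the motif comparison with 18 fixed words and the 20 fixed gene lists need a genome or annotation of hg19. The gene table at hand is of assembly GRCh38.p14, so none of its positions were used, no peak was assigned to a gene, and these planned parts were not run. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.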

Results

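Chromatin binding of JMJD1C, a JmjC-domain protein of the histone demethylase family, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kasumi-1 cells. Kasumi-1 is an established line of acute myeloid leukaemia that carries the RUNX1-RUNX1T1 fusion. The series holds 11 libraries from 4 leukaemia lines. There are 4 JMJD1C libraries, 4 libraries of the basic helix-loop-helix transcription factor LYL1, and 3 inputs. Each combination of line and target has 1 library, so no spread between replicates can be given. The question named by the design is where JMJD1C binds in Kasumi-1 cells, and the peak list of that library was analysed. The other 10 libraries, which include the Kasumi-1 input and the LYL1 and JMJD1C libraries of HL-60, NB4 and THP-1, were not analysed here, so no comparison between lines or factors is given. The JMJD1C library held 29330355 tags, of which 19897991 were left after the peak caller kept 1 tag per position. The authors called peaks in this library alone, without a control. Fold enrichment therefore compares each summit with a background from the same library and not with input DNA. That background, from the 10 kb around the peak, includes the peak's own tags, which can lower the fold of long and tag-rich peaks.

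JMJD1C binding was called at 36191 sites in Kasumi-1 cells, all on chromosomes 1 to 22, X and Y of hg19. The sites were narrow, with a median length of 477 bp (quartiles 359 and 668 bp), and together covered 20.4 Mb. They held 9.0% of the filtered tags (95% exact Clopper-Pearson interval 8.99% to 9.02%, counting error only). Tag density inside peaks was 11.9 times the average over the effective genome of 2.7 Gb. The median peak held 30 tags (quartiles 18 and 56) and had a fold enrichment of 10.87 (quartiles 8.62 and 14.66), as given by the authors' peak caller. A fold of at least 10 was reached by 21740 peaks (60.1%), of at least 20 by 3560 peaks (9.84%) and of at least 50 by 18 peaks. The list reached down to the caller's limit: 11335 peaks (31.3%) rested on 20 tags or fewer, and 5639 peaks (15.6%) had a score under 60, where the cutoff was 50. The tenth of the peaks with the most tags (3619 peaks) held 38.3% of all tags in peaks. Long peaks did not have the highest fold, which their own tags in the background can lower. The 216 peaks over 2 kb had a median fold of 9.49 against 11.56 for the 13572 peaks of 500 to 1000 bp, although they held a median of 334 against 50 tags. Across peaks, which are not independent replicates, length correlated with tag number (Spearman's rho 0.903) and hardly with fold (rho 0.0379).

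The 15 peaks with the highest fold enrichment on chromosomes 1 to 22 and X, the rule set for naming sites, were short and moderate in tag number. They had 36 to 174 tags, lengths of 227 to 591 bp and folds of 50.98 to 65.59. The strongest lay on chromosome 6 from 119558367 to 119558757, with 115 tags (exact Poisson 95% interval 94.9 to 138) and a fold of 65.59. It was followed by a peak on chromosome 21 from 35778196 to 35778530, with 80 tags (63.4 to 99.6) and a fold of 64.36. The third peak lay on chromosome 18 from 50318969 to 50319282, with 67 tags (51.9 to 85.1) and a fold of 63.85, and its nearest other peak was 1293 kb away. The peak on chromosome 3 from 196625582 to 196625815 held the most tags of the 15, 174 tags (149 to 202) at a fold of 55.77. Of the 15 peaks, 14 had no other peak within 10 kb, whereas 49.7% of all peaks in the list had one. Chromosome 9 contributed 5 of the 15. Of these, 2 started at 42819000 and 44070495, with folds of 51.65 and 53.9, and 2 started at 70076413 and 70327233, with folds of 55.14 and 54.18. A peak-free stretch of 18.4 Mb lies between these pairs, more than 1 Mb from each. The peak on X from 58330618 to 58330866 was within 1 Mb of a peak-free stretch of at least 3 Mb. Without an input, tags that collect on repeats could not be told from binding at any of the 15. None of the 15 was among the 1000 peaks with the most tags (0 of 15). The 10 kb background includes the peak's own tags and those of its neighbours. A ranking by fold can therefore favour isolated peaks with moderate tag numbers. The tops of both rankings overlapped little over the whole list: 100 peaks were shared between the 1000 of highest fold and the 1000 with the most tags, where independent rankings would share 27.6. Genes are not named for these sites because no annotation of hg19 was used here.

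The peaks with the most tags fell into different regions. The highest tag number was 6233 (exact Poisson 95% interval 6079 to 6390), in a peak of 6747 bp on chromosome 6 from 58773457 to 58780203, at a fold of 3. Next came chromosome 19 from 27731739 to 27740735, with 4857 tags and a fold of 5.64, and chromosome 18 from 18512647 to 18520426, with 4483 tags and a fold of 4.85. These 3 peaks lie within 1 Mb of a stretch of at least 3 Mb without any peak. There were 46 such stretches on 21 chromosomes, the longest of 30 Mb. Peaks within 1 Mb of one made up 3.75% of the list (1358 peaks) and 7.01% of the tags in peaks, but 26 of the 50 peaks with the most tags. The median fold of these 26 was 5.92, against 12.47 for the other 24. The background of these folds includes the peaks' own tags. The signal outside the peak, which includes tags of neighbouring peaks, had a median of 1758 tags per 10 kb in 14 of these 26. The other 12 were over 5000 bp long or had no recovered value, and several of the 14 lie next to each other on chromosome Y. On chromosomes 1, 4, 5, 7 and 18 the first peak began at position 9964 or 9965, and the one on chromosome 5 held 1322 tags. Without an input, tags that collect on repeats could not be told from binding at any of these sites or those below. Away from the long stretches, the chromosome 18 peak from 105669 to 111819 had 2952 tags (2846 to 3060) at a fold of 5.91. It was as long as several peaks beside the stretches, at 6151 bp, and its 10 kb background held 3078 tags. Chromosome 12 from 6444438 to 6447568 had 943 tags (884 to 1005) at a fold of 11.04. On chromosome 10, the peak from 94449580 to 94452184 had 780 tags (726 to 837) at a fold of 15.14. Chromosome 17 from 76587989 to 76589359 had 786 tags (732 to 843) at a fold of 18.79. Chromosome 1 from 26867955 to 26869453 had 740 tags (688 to 795) at a fold of 18.4. These tag-rich sites were chosen after their values were seen.

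**Figure D1:**
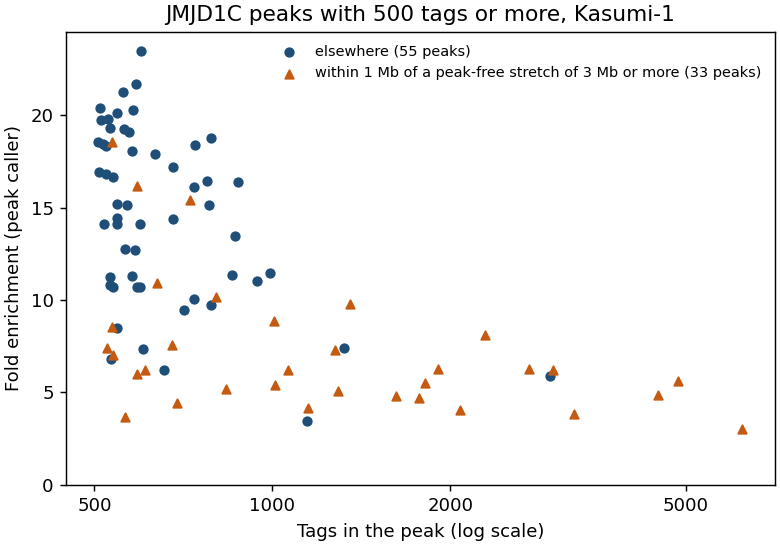
Fold enrichment from the peak caller against the number of tags (log scale) for the 88 JMJD1C peaks with 500 tags or more in Kasumi-1, 1 point per peak. The 33 triangles are peaks within 1 Mb of a peak-free stretch of 3 Mb or more, and they include 19 of the 22 peaks with 1000 tags or more, which have a median fold of 5.58.

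JMJD1C peaks were unevenly spread over the chromosomes. Chromosome 19, a gene-rich chromosome, had 30.3 peaks per Mb between its first and last peak, from 1792 peaks (4.95% of the list, 95% exact binomial interval 4.73% to 5.18%). Chromosome 22 followed with 24.4 per Mb and chromosome 17 with 23.6 per Mb. Spans include long peak-free stretches, such as 3.04 Mb on chromosome 17, so the order of close values is not settled. At the other end of the autosomes, chromosome 18, which is gene-poor, had 8.05 per Mb from 628 peaks (1.74%, 1.60% to 1.88%). The density on chromosome 19 was 3.77 times that on chromosome 18. Chromosomes 4 and 13 had 8.35 and 8.59 per Mb. The X chromosome had 5.26 peaks per Mb from 816 peaks, which is 0.417 of the 12.6 per Mb over all autosomes (0.389 to 0.447, from the exact binomial interval of the X share). Peaks with a fold of at least 10 made up 78.2% of those on X, 52.0% of those on chromosome 19 and 72.6% of those on chromosome 13. The background was at the caller's minimum in 39.2% of the peaks on X, 2.46% on chromosome 19 and 18.6% on chromosome 13. Fold divides by the local background, so a low background can raise it, and these shares do not compare binding strength. The signal around isolated peaks was lower on X, with a median of at most 61.5 tags per 10 kb against 78.2 on the autosomes. Peaks per Mb were not corrected for local tag depth, which also affects how many peaks are called. Chromosomes are not replicates, and the intervals cover counting error within this library.

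**Figure D2:**
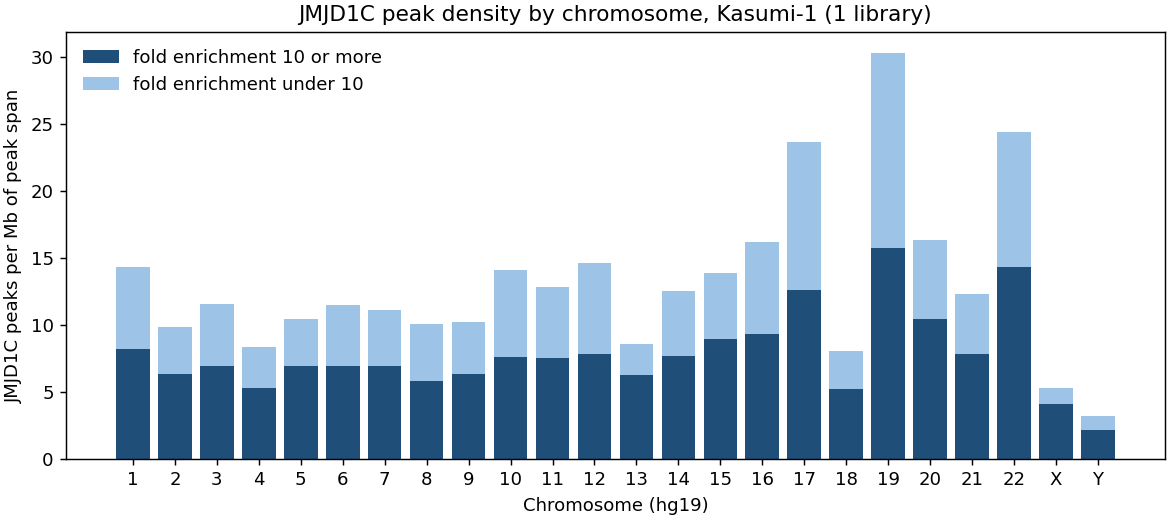
JMJD1C peaks per Mb of the span from the first to the last peak on each hg19 chromosome in the Kasumi-1 library, with peaks of fold 10 or more in dark and the rest in light blue. Chromosome 19 reached 30.3 and chromosome 18 8.05 per Mb.

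Peaks lay close together more often than random placement gave. Of the 36191 peaks, 17972 (49.7%, 95% exact binomial interval 49.1% to 50.2%) had another peak within 10 kb. Over 1000 random placements of the same peaks on the same chromosomes, outside the long peak-free stretches, the mean was 26.2% (range 25.3% to 27.0%), so the observed share was 1.89 times as high. The ratio was 2.77 for neighbours within 2 kb and 1.16 within 50 kb. At 50 kb the placements already gave a mean of 74.3%, which limits how high that ratio can be. The fall of the ratio with distance is therefore no measure of how clustering changes. With each peak placed inside its own 1-Mb window, which keeps the regional density, the mean was 37.0% and the ratio 1.34. Joining peaks up to 10 kb apart gave 25166 regions, of which 18219 held a single peak, 6567 held 2 to 4 peaks and 380 held 5 or more. The 32 regions with 10 or more peaks were split between the flanks of long peak-free stretches (17 regions) and other places (15 regions). Without an input, repeats that collect tags could not be told from binding in either set of regions. The 5 regions in other places with the most peaks were chosen after their values were seen. They began with the region on chromosome 2 from 132960480 to 133045658, with 25 peaks and 3107 tags. The region on chromosome 11 from 48830265 to 48899451 held 17 peaks with 961 tags, and the region on chromosome 9 from 66783112 to 66844012 held 14 peaks with 2107 tags. The region on chromosome 11 from 65624138 to 65687077 held 13 peaks with 664 tags, and the region on chromosome 19 from 12868447 to 12917598 held 12 peaks with 615 tags. Placements describe this library and are not replicates, so no p-value is given.

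**Figure D3:**
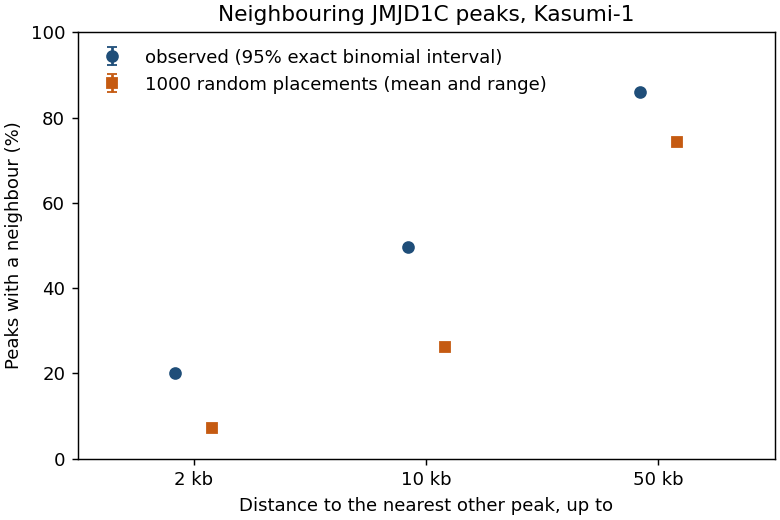
Percent of the 36191 Kasumi-1 JMJD1C peaks with another peak within 2, 10 or 50 kb (circles, 95% exact binomial interval) beside 1000 random placements (squares, mean and range), with bars smaller than the symbols. Observed shares were 20.1%, 49.7% and 85.9%, and the placements gave means of 7.26%, 26.2% and 74.3%.

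At the scale of 1 Mb, the median window with a peak held 10 peaks. The window with the most peaks lay on chromosome Y from 13 to 14 Mb, with 96 peaks, all of them beside a long peak-free stretch. Next was chromosome 17 from 73 to 74 Mb, with 73 peaks and 6879 tags. Of the 25 densest windows, 7 lay on chromosome 17, 4 on chromosome 19, 3 on chromosome 1, and 2 each on chromosomes 6, 11 and 16. Windows with 60 peaks lay on chromosome 11 from 65 to 66 Mb, chromosome 17 from 79 to 80 Mb and chromosome 19 from 2 to 3 Mb. The 2 windows on chromosome 6, from 26 to 27 Mb and from 28 to 29 Mb, held 55 and 56 peaks. The 7 windows on chromosome 17 lay at 40 to 41 Mb or between 73 and 81 Mb. There the median signal around isolated peaks was 97.9 tags per 10 kb from 40 to 50 Mb and 114 from 70 to 80 Mb. It was 72.3 on chromosome 6 from 20 to 30 Mb and 78.2 over the autosomes. Whether tag depth adds to the number of peaks in the densest windows was not tested.

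The signal around the peaks could be recovered from each peak's tags and score, since the caller derives its local background from the 10 kb around the peak. The signal outside the peak had a median of 99.8 tags per 10 kb (quartiles 76.2 and 137.7). The peak's own tags made up a median of 22.1% of the recovered background per 10 kb. For peaks at the caller's minimum this share is a lower limit, because the minimum replaces a smaller number of tags. Among the 10968 peaks with no other peak within 20 kb, and away from long peak-free stretches, the median was 77.4 tags per 10 kb. It differed between segments of several chromosomes. On chromosome 12 beyond 100 Mb it was 128 tags per 10 kb, 1.66 times that on the rest of the chromosome (bootstrap 95% interval over peaks 1.53 to 1.76, 141 peaks). On chromosome 3 beyond 180 Mb the ratio was 1.43 (1.35 to 1.57), on chromosome 8 beyond 120 Mb 1.35 (1.24 to 1.45), and on chromosome 10 before 90 Mb 1.35 (1.249 to 1.441). Lower signal was seen on chromosome 17 before 25 Mb, with a ratio of at most 0.604 (0.568 to 0.645) to a rest of the chromosome that was itself high at 101 tags per 10 kb, on chromosome 9 before 30 Mb, at most 0.777 (0.740 to 0.825), and on chromosome 2 beyond 200 Mb, at most 0.818 (0.784 to 0.845). These are upper limits because 54.2%, 56.8% and 45.9% of the isolated peaks there were at the caller's genome-wide minimum of 73.7 tags per 10 kb. With another reference, the autosomal isolated peaks with as many peaks within 500 kb, the ratios were 1.47 on the chromosome 12 segment, 1.26 on that of chromosome 3, 1.23 on that of chromosome 10 and 1.22 on that of chromosome 8. They were 0.761, 0.896 and 0.838 on those of chromosomes 17, 9 and 2, and 0.839 on X. The signal there is an upper limit, but the matched reference can include peaks at the caller's minimum too. These ratios are therefore not strict upper limits. The peaks' fold, which divides by the local background from which this signal was recovered, moved the other way. On chromosome 12 beyond 100 Mb the median fold was 8.99, against 10.88 on the rest of the chromosome. On chromosome 17 before 25 Mb it was 12.34, against 9.82. An opposite movement can follow from that division, so it is no separate observation. Among the 266 autosomal windows of 10 Mb with at least 15 isolated peaks, the highest median was 138 tags per 10 kb (111 to 165, 31 peaks), on chromosome 4 from 50 to 60 Mb. The lowest was at most 58.8 (54.0 to 62.0, 32 peaks), on chromosome 13 from 30 to 40 Mb. On chromosome 15 from 20 to 50 Mb the 3 window medians were at most 62.3 to 64.8. The segments were chosen after their values were seen, others also differ, and peaks are not replicates.

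**Figure D4:**
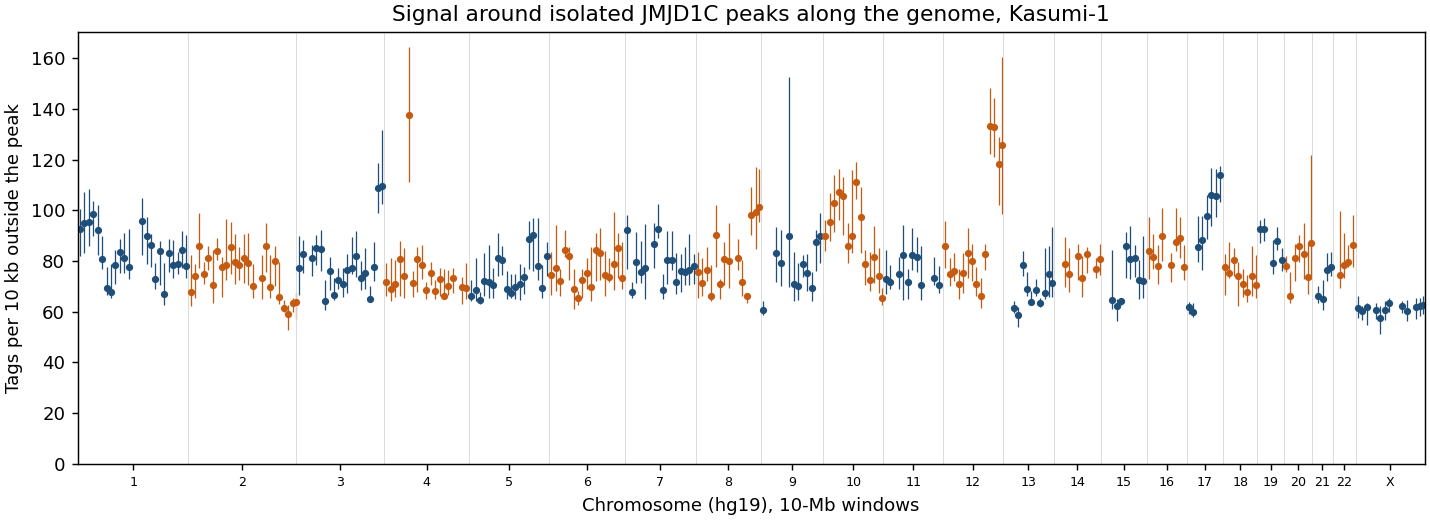
Median tags per 10 kb outside the peak, for isolated JMJD1C peaks in 10-Mb windows along the hg19 chromosomes of the Kasumi-1 library (points, windows with at least 15 isolated peaks), with bootstrap 95% intervals over peaks as bars and neighbouring chromosomes in alternating colours. Points near 60 are upper limits set by the caller's minimum background, the 4 windows of chromosome 12 beyond 100 Mb lie between 118 and 133, and the highest point, 138, is chromosome 4 from 50 to 60 Mb.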

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

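Alternatives that leave out peaks beside long peak-free stretches, that change the placement, or that concern X were chosen after seeing the data. The direction of the neighbour excess and of the deficit on X held under each alternative that was run. The size of the neighbour excess moved under each of them, and that of the deficit on X under 2 of 4. With only the peaks scoring above the median, 18094 were left, with a median fold of 14.01 and 6.99% of the tags; with a fold of 10 or more, 21740 peaks were left, with a median fold of 13.73 and 6.05% of the tags. These follow from the smaller lists. The filter on chromosomes removed no peak and so tests nothing. Without the peaks beside long stretches the number was 34833, the median fold 10.88 and the share of tags 8.37%. The share of peaks with a neighbour was 20.1% within 2 kb, 85.9% within 50 kb, 25.9% among peaks of fold 10 or more and 49.0% without the peaks beside long stretches. The ratio to placement was 2.77 within 2 kb, 1.16 within 50 kb, 1.60 for fold 10 or more, 1.92 without peaks beside long stretches, 2.01 when placed over the whole span and 1.34 when placed within the same 1-Mb window. The last value shows that part of the excess over random placement is regional density. The X to autosome ratio of peaks per Mb was 0.368 among peaks scoring above the median and 0.547 at a fold of 10 or more, and the cause was not tested; it stayed within the interval of the main value at 0.395 without the peaks beside long stretches and at 0.440 with the stretches taken out of the spans. Of the 22 alternatives planned, the 16 on promoters, motifs and gene lists were not run, because no annotation of hg19 was used here. No paired analysis was possible because only 1 library was analysed here. Depth limits the weakest sites: with the whole library at 50% of its depth, 63.1% of the autosomal peaks would still pass the cutoff in simulated draws, and at 80% of the depth 85.1%.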

Other observations

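All patterns below were chosen after the data were seen. The tests were chosen after their results were seen, except that of peak-dense surroundings, whose prediction was written before its own value was known.

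The higher signal around isolated peaks on chromosome 12 beyond 100 Mb was set against 2 explanations. Peak-dense surroundings are argued against as the whole cause, since the ratio was 1.47 (1.41 to 1.57) against autosomal isolated peaks with as many peaks within 500 kb. DNA copy number of the cell line remains a candidate explanation: the signal rose from 83.0 tags per 10 kb between 95 and 100 Mb (26 peaks) to 146 between 100 and 105 Mb (14 peaks), a ratio of 1.76 (1.36 to 1.98). The boundary was picked from the same data, and the Kasumi-1 input, which would show the step without the antibody, was not analysed here.

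Fewer peaks per Mb on X might follow from lower tag depth there. The surrounding signal of isolated X peaks was at most 0.787 of that on the autosomes (0.771 to 0.798). With the tags of the autosomal peaks drawn down to 50% and the caller's minimum background kept at 73.7 tags per 10 kb, 52.0% were still called, against the observed ratio of 0.417 (0.389 to 0.447) of X to autosomes. Drawn down to 80%, near the upper limit measured on X, 82.5% were still called. Both are assumed depths, and the true depth on X is hidden by the caller's minimum, with 59.2% of isolated X peaks at it. Lower depth and fewer binding sites on X cannot be told apart here.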
